A study of Rattus norvegicus with 23 samples.

How the data were processed

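The measurement was RNA-seq of the heart apex of 23 Lewis rats, 1 library per rat. Per the labels' protocols, RNA was isolated with Trizol, polyadenylated RNA was purified on poly(A) beads, and directional sequencing libraries were prepared. The deposited values are whole-number read counts per gene, 1 file per library, and the file values are not normalized. Per the submitters' processing notes, STAR 2.4.2a, Picard and HTSeq 0.6.1p1 were used with the rat genome build Rnor_5.0. The role of Picard, the annotation release, the strand setting of the counter and any removal of duplicate reads are not given in the sources used here, so reads of overlapping or antisense genes, or of near-identical gene copies, may be assigned imperfectly. Each deposited count file held 26405 Ensembl rat gene identifiers and 5 summary lines. The summary lines (reads in no feature, ambiguous reads, non-unique alignments and others) were left out of library sizes and tests. Reads in no feature came to 10.6 to 21.5% and ambiguous reads to 0.872 to 1.97%. Non-unique alignments numbered 0.390 to 10.7 per counted read.

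Library depth was 7391929 to 12444980 counts in genes, with a median of 9831294, and 13916 to 15003 genes had at least 1 count. The precision of a level follows from these totals: in CD-HR5, the library with the lowest total, 7 counts of ENSRNOG00000021670 equalled 1.16 CPM. The counts come from PCR-amplified libraries with no molecular identifiers named, so counting error understates the error of a single library, and the spread between rats was used for every test.

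The files carry gene identifiers with no gene names, and the reference table at hand (assembly GRCr8) held 0 Ensembl rat identifiers. Genes are therefore given by identifier, with at most 2 that rose and 2 that fell per comparison, and without coordinates. For the same reason the 43 gene lists fixed before the data were examined (cardiac stress, matrix, metabolism, immune and other cell markers) could not be matched, and 0 of them were tested. The rule for the genes the text names was also fixed before the data were examined: among genes with a mean of at least 1 CPM over the 23 libraries, those with the largest rise and the largest fall past the threshold, or, where none passed, the 3 with the smallest p. The rule allowed 10 per direction, which the lack of names reduced to 2. Its parts on gene lists and on a fixed set of cardiac and clock genes could not be applied.

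Groups and replicate numbers came from the sample titles. Pairs of libraries of the same group were compared for duplicate deposits by a chi-square test over genes with at least 10 counts in the pair. The lowest chi-square per degree of freedom was 8.38, so no pair agreed within sampling noise. Genes were filtered with filterByExpr on the 4 groups, which left 11568 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit with robust estimation, glmQLFTest), in 1 fit of all 23 libraries so that the groups shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Every adjusted p in the text is from this edgeR test unless another tool is named. The standard error of a log2 fold change was taken as its size divided by the square root of the test's F value. CPM values are TMM-scaled, and group values are mean ± SD. Log2 CPM for principal components and scores used a prior count of 2. Differences between groups in single measures of the libraries were tested with two-sided exact permutation tests.

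The 8 comparisons were the donor kidney's disease in each kind of recipient, the recipient's disease with each kind of donor kidney, disease in both against neither, the average donor and recipient effects, and the donor by recipient interaction. The same code was tested on simulated counts with 200 genes changed by known folds. With a simulated 2-fold change, 75.8% of changed genes were recovered for the donor comparison in healthy recipients (11459 genes), 68.7% for that in CKD recipients (11431 genes), 68.2% for the recipient comparison with healthy donors (11441 genes), 94.0% for the averaged recipient comparison (11465 genes) and 44.6% for the interaction (11485 genes). At 1.5-fold the corresponding shares were 34.8%, 28.1%, 23.9%, 64.2% and 12.3%. For the averaged donor comparison (11450 genes) 85.1% were recovered at 2-fold and 67.2% at 1.5-fold. Of all calls in these simulations, 1.54 to 8.51% fell on unchanged genes, and 1 simulated data set with no change gave 0 calls in each of the 8 comparisons. Genes were drawn independently and without a batch, so these values do not cover false calls from correlated genes or a batch.

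The deposited animal names begin with 12 or 13. All 12 healthy recipients have the prefix 13, while 9 CKD recipients have 12 and 2 have 13. The meaning of the prefix is not given in the sources used here. It was treated as a possible batch, as a covariate and by restriction to 1 prefix. The other alternatives fixed before the data were examined were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1) with sample weights, no filter on low counts, a filter of at least 1 CPM in at least 5 libraries, the replicate number as a block, 2 surrogate variables (sva 3.50.0), each library left out in turn, and only the 2 groups compared. After the data were seen, 3 more were added: leaving out the 3 libraries that stand apart in quality measures (HD-CR2, CD-CR1 and CD-HR5), the log2 ratio of non-unique alignments to counted reads as a covariate, and the share of counts in the 10 most abundant genes as a covariate. Plots were drawn with matplotlib 3.10.9.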

Results

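The transcriptome of the heart apex was measured in rats 6 weeks after kidney transplantation, in a design that crossed the health of the kidney donor with the health of the recipient. Chronic kidney disease (CKD) had been induced by ablation of part of the renal mass, accelerated with L-NNA, an inhibitor of nitric oxide synthase (200 mg/L in drinking water), and with 6% NaCl in the chow. This treatment ended at a proteinuria of 200 mg per 24 h. Rats with CKD entered the transplantation protocol once proteinuria was 100 mg per 24 h without that treatment. Each recipient received a left kidney in the orthotopic position and lost its right native kidney 10 to 14 days later. The 4 groups were a healthy donor kidney in a healthy recipient (HD-HR, n = 6), a CKD donor kidney in a healthy recipient (CD-HR, n = 6), a healthy donor kidney in a CKD recipient (HD-CR, n = 5) and a CKD donor kidney in a CKD recipient (CD-CR, n = 6). All rats were of the inbred Lewis strain, in which transplants between animals are isografts.

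Depth was similar in the 4 groups. The total count in genes per library ran from 7605675 to 11484365 in HD-HR, from 7391929 to 12169291 in CD-HR, from 9212531 to 11373022 in HD-CR and from 7801127 to 12444980 in CD-CR. The single most abundant gene took 13.1 to 19.6% of the counts, and the 10 most abundant together took 48.8 to 68.6%. That share was lowest in CD-CR1 (48.8%) and HD-CR2 (51.4%). Non-unique alignments per counted read, on a log2 scale, averaged 0.29 in CKD recipients (n = 11) and 1.24 in healthy recipients (n = 12), with an exact permutation p = 0.00976 and a Benjamini-Hochberg value of 0.0936 over 12 such tests. Reads in no feature were 14.1% in CKD and 16.2% in healthy recipients (exact p = 0.0156, adjusted 0.0936). Neither difference passed the correction. The first principal component held 22.2% of the variance and the second 15.3%. On the first, HD-CR averaged -26.1 ± 13.6 (SD, n = 5), CD-CR -9.07 ± 11.3 (n = 6), HD-HR 10.3 ± 17.9 (n = 6) and CD-HR 20.6 ± 11.5 (n = 6).

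**Figure D1:**
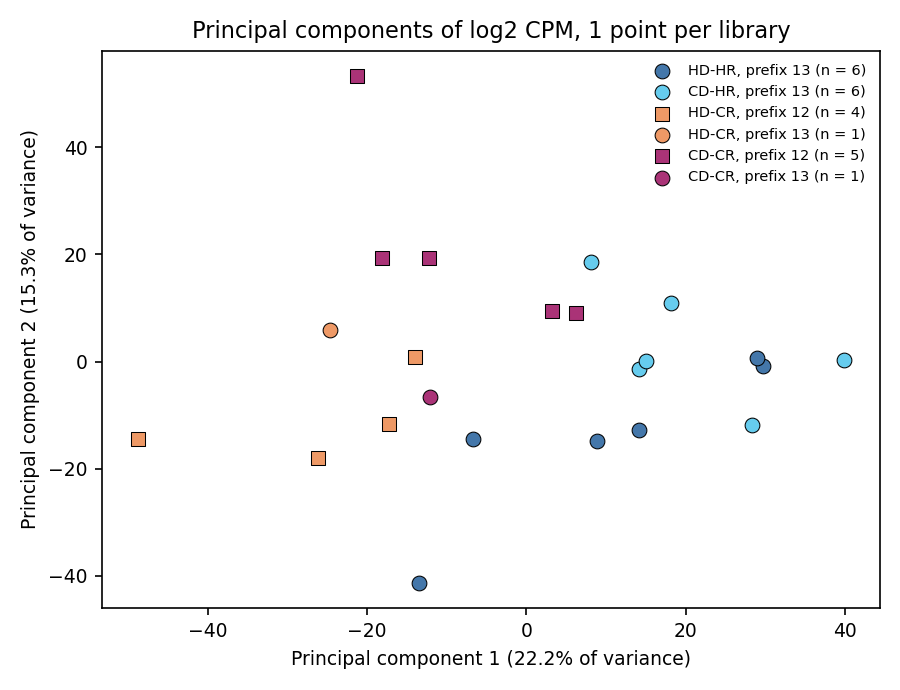
Scores of the 23 libraries on principal components 1 and 2 of log2 CPM (arbitrary units; the axes give the share of variance). Colours mark the 4 groups, squares and circles the prefixes 12 and 13 of the deposited animal names. CKD recipients lie mostly to the left, and CD-CR1 lies alone at 53.3 on component 2.

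Whether CKD of the recipient left a mark on the heart 6 weeks after transplantation was addressed by comparing CKD with healthy recipients, averaged over both kinds of donor. Recipient CKD here includes the ablation, L-NNA and NaCl that induced it, whose own effects on the heart cannot be told apart. Of 11568 genes tested, 1483 (12.8%) were called, 705 of which rose and 778 fell in CKD recipients. The changes were mostly small: the median log2 fold change was 0.58 among genes that rose and -0.44 among genes that fell, and 139 and 51 genes moved by at least 2-fold. The called genes together held 12.6% of the CPM. The clearest rise by p was that of ENSRNOG00000016182, with 1.37 ± 1.35 CPM in HD-HR (SD, n = 6), 1.44 ± 1.01 in CD-HR (n = 6), 10.4 ± 4.10 in HD-CR (n = 5) and 15.3 ± 4.46 in CD-CR (n = 6). Its log2 fold change was 3.16 ± 0.33 (SE, adjusted p = 2.74e-05 by edgeR), and the lowest CKD recipient (5.69 CPM) lay above the highest healthy recipient (3.90 CPM). ENSRNOG00000048472 had the largest fitted rise, 3.31 ± 0.81 (adjusted p = 0.0142), but its level was low and CD-CR6 stood apart, with 25.4 CPM against at most 4.92 in the other CD-CR libraries. Without CD-CR6, or without CD-CR1, CD-CR2 or CD-CR4, it no longer passed the filter on low counts and was not tested. ENSRNOG00000021670 fell by 2.05 ± 0.36 on the log2 scale (adjusted p = 0.00117), from 2.41 ± 1.56 CPM in HD-HR and 1.88 ± 1.15 in CD-HR to 0.401 ± 0.295 in HD-CR and 0.641 ± 0.397 in CD-CR. ENSRNOG00000007539 fell by 2.35 ± 0.60 (adjusted p = 0.0187), with a wide spread in the healthy recipients (66.8 ± 75.9 CPM in HD-HR, where HD-HR1 had 207.7 CPM, and 48.0 ± 51.7 in CD-HR) and 12.2 ± 6.61 and 10.2 ± 8.64 CPM in HD-CR and CD-CR.

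The recipient difference was nearly confounded with the prefix of the animal names. With the prefix as a covariate 6 genes were called, and among libraries of prefix 13 alone, which hold 2 CKD recipients, 0 genes were called and ENSRNOG00000048472 was at 1.68, while by limma-voom it was at 2.145 and passed. Of the 1483 genes, 1472 kept their direction with the covariate, with a median log2 change of 0.49 before and 0.53 after in the original direction, while the median SE rose from 0.132 to 0.245. That fit sets the 2 CKD recipients of prefix 13 against the healthy recipients. These libraries also helped choose the 1483 genes, so part of the kept direction and size is built in. With that covariate the log2 fold changes were 2.57 for ENSRNOG00000016182, 2.80 for ENSRNOG00000048472, -1.91 for ENSRNOG00000021670 and -1.64 for ENSRNOG00000007539, none of which passed. With 2 surrogate variables 6 genes were called, and the median change of the 1483 genes fell from 0.49 to 0.24 (median SE 0.132 before and 0.151 after), with log2 fold changes of 2.25 for ENSRNOG00000048472, -1.93 for ENSRNOG00000007539 and -1.33 for ENSRNOG00000021670, which did not pass. The first surrogate variable itself averaged 0.128 ± 0.177 in CKD recipients (SD, n = 11) and -0.117 ± 0.176 in healthy recipients (n = 12; exact permutation p = 0.00298). Leaving out the 3 libraries that stand apart gave 973 genes, a setting in which ENSRNOG00000007539 no longer passed (-2.15), leaving out CD-HR4 gave 900 and leaving out HD-CR4 gave 860.

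**Figure D2:**
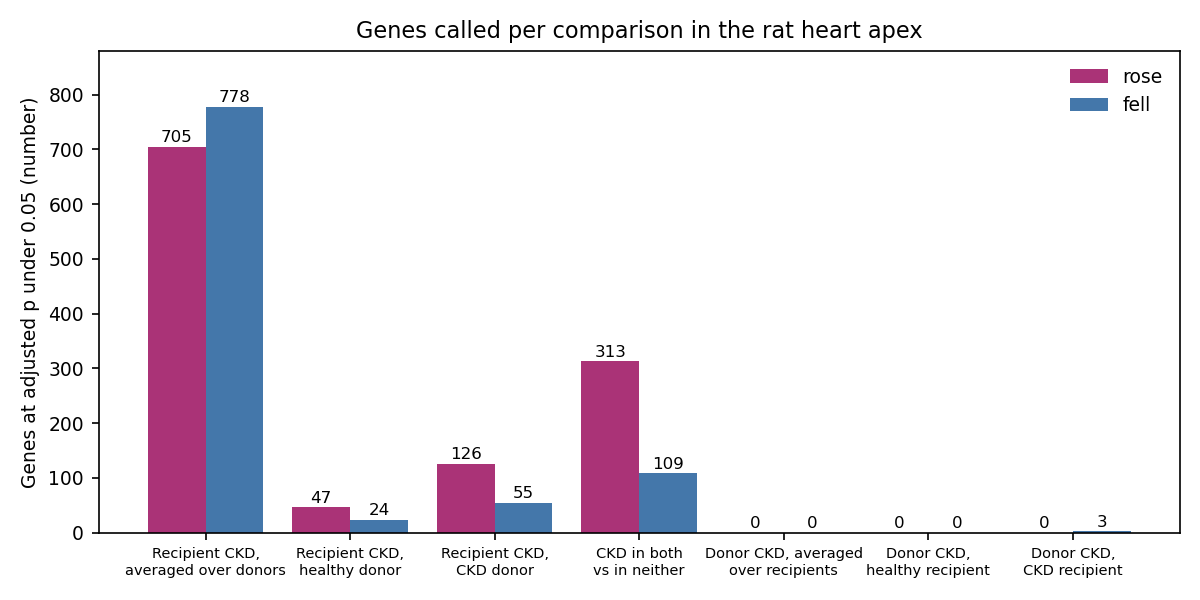
Number of genes called at an adjusted p under 0.05 by edgeR (vertical axis) in 7 comparisons (horizontal axis), split into genes that rose and fell with CKD. Recipient CKD gave 705 and 778 genes averaged over donors, and the donor comparisons gave 0, 0 and 3.

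With a healthy donor kidney, CKD recipients (HD-CR, n = 5) differed from healthy recipients (HD-HR, n = 6) in 71 genes, of which 47 rose and 24 fell. The largest rise was that of ENSRNOG00000028064, from 0.864 ± 0.486 CPM in HD-HR to 12.3 ± 8.26 in HD-CR (13.6-fold, log2 3.77 ± 0.74, adjusted p = 0.0299 by edgeR). ENSRNOG00000006151 rose from 0.209 ± 0.171 to 2.00 ± 0.643 CPM (8.94-fold, adjusted p = 0.0222). ENSRNOG00000021670 fell from 2.41 ± 1.56 to 0.401 ± 0.295 CPM (log2 -2.49 ± 0.54, adjusted p = 0.0309) and ENSRNOG00000007030 from 2.07 ± 0.613 to 0.482 ± 0.238 CPM (log2 -2.04 ± 0.39, adjusted p = 0.0192). The prefix covariate left 3 called genes, libraries of prefix 13 alone (1 HD-CR library) gave 10, 2 surrogate variables gave 0, and leaving out the 3 libraries that stand apart gave 111, while DESeq2 called 259, limma-voom 167, a fit of the 2 groups alone 306, and a fit with the share of the 10 most abundant genes as a covariate 47. The count fell to 24, 14, 10 or 33 without HD-HR2, HD-HR3, HD-HR4 or HD-HR5, and to 47, 36, 6 or 5 without HD-CR2, HD-CR3, HD-CR4 or HD-CR5, and each of the 4 named genes failed to pass without HD-HR4, HD-CR4 or HD-CR5. ENSRNOG00000028064 and ENSRNOG00000006151 also failed without HD-HR2 or HD-HR3, ENSRNOG00000028064 without HD-HR1, and ENSRNOG00000021670 without HD-HR2, HD-HR5, HD-CR1 or HD-CR3, by limma-voom or with the ratio of non-unique alignments as a covariate. None of the 4 passed with the prefix covariate, within prefix 13 or with 2 surrogate variables, and the last reduced ENSRNOG00000028064 to 2.63, ENSRNOG00000021670 to -1.68 and ENSRNOG00000007030 to -1.25.

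With a CKD donor kidney, CKD recipients (CD-CR, n = 6) differed from healthy recipients (CD-HR, n = 6) in 181 genes, of which 126 rose and 55 fell. ENSRNOG00000028311 rose from 0.776 ± 0.527 CPM in CD-HR to 12.1 ± 2.97 in CD-CR (15.4-fold, log2 3.94 ± 0.55, adjusted p = 0.00121 by edgeR). It also stood at 10.3 ± 2.32 CPM in HD-CR, against 2.89 ± 3.40 in HD-HR. ENSRNOG00000048472 rose from 0.309 ± 0.269 to 5.92 ± 9.70 CPM (adjusted p = 0.03), with CD-CR6 again at 25.4 CPM. ENSRNOG00000013408 fell from 5.15 ± 3.66 to 1.44 ± 0.443 CPM (log2 -1.84 ± 0.39, adjusted p = 0.0196) and ENSRNOG00000042516 from 2.11 ± 1.69 to 0.644 ± 0.255 CPM (log2 -1.77 ± 0.45, adjusted p = 0.0412). Among prefix 13 alone (1 CD-CR library) and with the prefix as a covariate 0 genes were called, with 2 surrogate variables 8, without the 3 libraries that stand apart 18, with the ratio of non-unique alignments as a covariate 109, with the share of the 10 most abundant genes 334, in the 2 groups alone 32, by limma-voom 115 and by DESeq2 449. In that single CD-CR library of prefix 13, ENSRNOG00000048472 had a log2 fold change of -0.37, and the count of genes was 48, 92, 103, 61 or 79 without CD-HR4, CD-HR5, CD-HR6, CD-CR1 or CD-CR2 and 359 or 329 without CD-HR1 or CD-CR4. ENSRNOG00000042516 did not pass without CD-HR4, CD-HR5, CD-HR6, CD-CR1, CD-CR2, CD-CR3 or CD-CR6, ENSRNOG00000013408 without CD-HR4, and ENSRNOG00000048472 without CD-HR3, CD-HR4, CD-HR5 or CD-HR6, while ENSRNOG00000028311 passed without each library in turn. By limma-voom and without the 3 libraries that stand apart, ENSRNOG00000048472 (log2 1.84 and 4.14), ENSRNOG00000013408 (-1.54 and -1.83) and ENSRNOG00000042516 (-1.45 and -1.64) did not pass, nor did ENSRNOG00000048472 with no filter on low counts, or ENSRNOG00000013408 in the 2 groups alone or with the ratio of non-unique alignments. None of the 4 passed with the prefix covariate or within prefix 13, and with 2 surrogate variables ENSRNOG00000028311 alone did, with ENSRNOG00000048472 at 3.16, ENSRNOG00000013408 at -1.30 and ENSRNOG00000042516 at -0.80.

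These recipient comparisons share no library, so their agreement could be counted directly. Among the called genes, 23 rose in both, where 0.51 would be expected of independent lists, and 6 fell in both, where 0.11 would be expected. Both lists come from 1 fit with a shared estimate of each gene's spread, so they are not fully independent and these expected values may be too low. Of the 71 genes called with a healthy donor, 69 (97.2%) had the same direction with a CKD donor, and of the 181 called with a CKD donor, 177 (97.8%) had the same direction with a healthy donor. Across all genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson correlation of 0.641 and a Spearman correlation of 0.564. In 100 relabellings of the libraries within each donor kind the Pearson correlation reached at most 0.434. Both comparisons are confounded with the prefix in the same way. The comparisons differed in their counts, 71 and 181, but the test of the difference itself, the interaction, called 1 gene. On simulated counts that test recovered 44.6% of 2-fold and 12.3% of 1.5-fold changes, so differences between the responses could be missed.

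**Figure D3:**
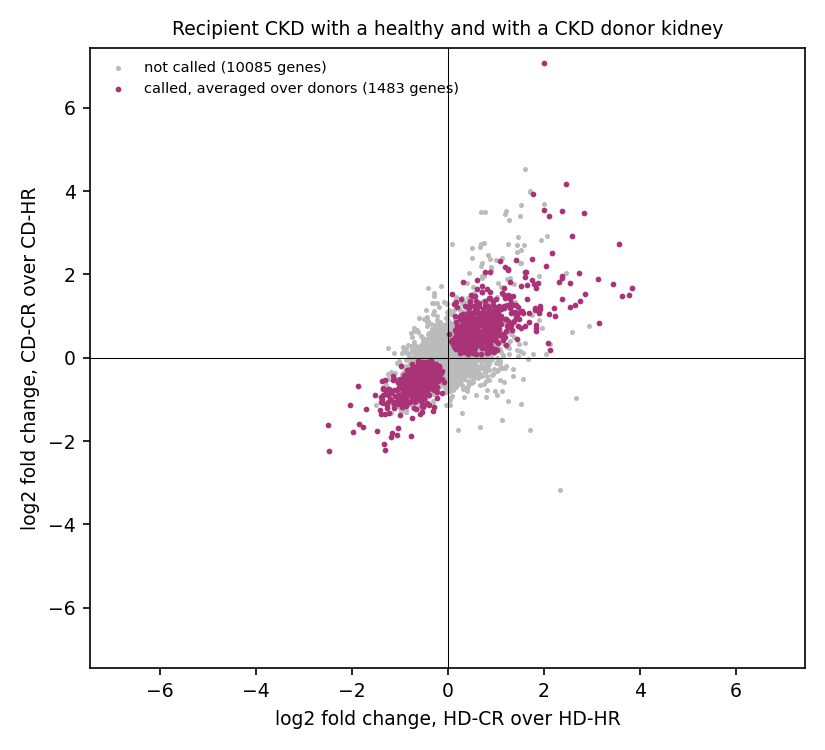
Log2 fold change of each of 11568 genes for recipient CKD with a healthy donor kidney (horizontal axis) and with a CKD donor kidney (vertical axis). The 1483 genes called averaged over donors are coloured, and each of them has the same sign on both axes, which choosing genes by the average of the plotted changes favours by itself.

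Hearts with CKD in both donor and recipient (CD-CR, n = 6) were compared with those with CKD in neither (HD-HR, n = 6). This gave 422 genes, of which 313 rose and 109 fell, and 332 of them were also among the 1483 genes of the averaged recipient comparison. That comparison uses the same CD-CR and HD-HR libraries, so an overlap is built in. The largest rises were those of ENSRNOG00000048472, from 0.136 ± 0.190 to 5.92 ± 9.70 CPM (adjusted p = 0.00755 by edgeR), and ENSRNOG00000010666, from 0.291 ± 0.438 to 7.62 ± 9.39 CPM (adjusted p = 0.0229, with CD-CR1 at 25.8 CPM). Both started from few counts, so their fitted folds are imprecise. ENSRNOG00000042516 fell from 2.63 ± 0.982 to 0.644 ± 0.255 CPM (log2 -2.03 ± 0.44, adjusted p = 0.00949) and ENSRNOG00000021670 from 2.41 ± 1.56 to 0.641 ± 0.397 CPM (log2 -1.89 ± 0.48, adjusted p = 0.0236). With the prefix as a covariate and within prefix 13 (1 CD-CR library) 0 genes were called, with 2 surrogate variables 88, without the 3 libraries that stand apart 219, and by DESeq2 651. Leaving out HD-HR4, CD-CR1 or CD-CR6 gave 250, 258 or 227 genes. ENSRNOG00000010666 did not pass without CD-CR1 (log2 3.79), HD-HR1, HD-HR3 or HD-HR5, and ENSRNOG00000021670 did not pass without HD-HR4, HD-HR5, CD-CR1, CD-CR2 or CD-CR6. By limma-voom ENSRNOG00000048472 (log2 3.35), ENSRNOG00000010666 (4.04) and ENSRNOG00000021670 (-1.45) did not pass, without the 3 libraries that stand apart ENSRNOG00000010666 (3.79) and ENSRNOG00000021670 (-1.83) did not, and ENSRNOG00000021670 also failed with the ratio of non-unique alignments (-1.69). None of the 4 passed with the prefix covariate, within prefix 13 or with 2 surrogate variables, and within prefix 13 ENSRNOG00000048472 was at 0.82 and ENSRNOG00000010666 at 1.75. With 2 surrogate variables ENSRNOG00000010666 was at 2.57 and ENSRNOG00000042516 at -1.27.

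Whether a CKD kidney changes the heart of a healthy recipient was addressed by CD-HR (n = 6) against HD-HR (n = 6). The edgeR test called 0 of 11568 genes, with 879 genes at an unadjusted p under 0.05 where 578 would be expected by chance and a smallest adjusted p of 0.398. DESeq2 called 11 genes and limma-voom 0. The 3 genes with the smallest p did not pass. ENSRNOG00000008168 stood at 1.91 ± 0.435 CPM in HD-HR and 0.876 ± 0.196 in CD-HR, ENSRNOG00000001766 at 28.9 ± 9.27 and 60.1 ± 23.1 CPM, and ENSRNOG00000002224 at 13.1 ± 2.02 and 20.7 ± 6.32 CPM, each with an adjusted p of 0.398. Without CD-HR6, ENSRNOG00000001766 passed (log2 1.22) and the count was 1, and DESeq2 passed both ENSRNOG00000001766 and ENSRNOG00000002224. On simulated counts of this comparison 34.8% of genes changed by 1.5-fold were recovered, so changes of that size could be missed.

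In CKD recipients the donor comparison, CD-CR (n = 6) against HD-CR (n = 5), called 3 genes, all lower with a CKD donor kidney. ENSRNOG00000011557 fell from 7.04 ± 2.23 CPM in HD-CR to 1.68 ± 0.996 in CD-CR (log2 -2.09 ± 0.32, adjusted p = 0.00502 by edgeR), and the 5 HD-CR libraries all lay above the 6 CD-CR libraries. ENSRNOG00000011955 fell from 3.39 ± 1.48 to 0.681 ± 0.280 CPM (log2 -2.27 ± 0.39, adjusted p = 0.0156). It was at 0.936 ± 0.436 CPM in HD-HR and 0.402 ± 0.292 in CD-HR, so HD-CR stood apart for this gene rather than CD-CR. The third gene fell from 16.3 ± 4.69 to 4.86 ± 1.87 CPM (log2 -1.75 ± 0.27, adjusted p = 0.00502) and was at 7.94 ± 2.84 CPM in HD-HR and 9.14 ± 2.60 in CD-HR. At an unadjusted p under 0.05 there were 961 genes, where 578 would be expected. Among the 9 libraries of prefix 12, 2 genes were called, without the 3 libraries that stand apart 12, with the share of the 10 most abundant genes as a covariate 5, in the 2 groups alone 7, by limma-voom 14 and by DESeq2 36, and leaving out HD-CR2 gave 18. ENSRNOG00000011955 did not pass within prefix 12 (log2 -2.03), by limma-voom (-2.08), with 2 surrogate variables (-2.20), or without HD-CR1, HD-CR4, HD-CR5, CD-CR2, CD-CR4 or CD-CR5, where its log2 fold change lay between -2.26 and -2.15.

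Averaged over recipients, CKD of the donor gave 0 called genes by edgeR, although 1477 genes had an unadjusted p under 0.05, where 578 would be expected, and the smallest adjusted p was 0.0572. DESeq2 called 226 genes and limma-voom 1. The 3 genes with the smallest p, none of which passed, were ENSRNOG00000011955 (log2 -1.74 ± 0.30, adjusted p = 0.0572), ENSRNOG00000018224 (log2 -2.29 ± 0.44, adjusted p = 0.0654) and ENSRNOG00000008837 (log2 -1.88 ± 0.36, adjusted p = 0.0654). ENSRNOG00000018224 stood at 2.63 ± 2.28 CPM in HD-HR, 0.645 ± 0.794 in CD-HR, 5.40 ± 2.79 in HD-CR and 0.895 ± 0.405 in CD-CR. The count was 46 without HD-CR2, 35 without CD-HR6, 16 without HD-HR2, 5 without CD-HR1, 2 without HD-HR1 or HD-HR3, 1 without CD-CR1 or CD-CR6, and 6 without the 3 libraries that stand apart. With no filter on low counts 1 gene was called, and with the share of the 10 most abundant genes as a covariate 16. Over 34 alternatives ENSRNOG00000011955 passed in 11, ENSRNOG00000018224 in 6 and ENSRNOG00000008837 in 6, and the log2 change of ENSRNOG00000008837 was -1.003 with 2 surrogate variables.

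Whether the donor effect differed between kinds of recipient was tested as the donor by recipient interaction, which called 1 gene, with 377 genes at an unadjusted p under 0.05 against 578 expected. ENSRNOG00000011557 had a log2 donor effect of -2.09 in CKD recipients and 0.54 in healthy recipients (adjusted p = 0.703 for the latter), where it stood at 3.21 ± 1.03 CPM in HD-HR (n = 6) and 4.77 ± 1.35 in CD-HR (n = 6). The difference of the effects was -2.64 ± 0.44 (adjusted p = 0.0304 by edgeR). Its call was lost without any 1 of HD-HR2, HD-HR4, HD-HR6, CD-HR2, CD-HR3, CD-HR5, HD-CR1, HD-CR2, HD-CR3, CD-CR3, CD-CR4 or CD-CR6, each of which left 0 genes, and without the 3 libraries that stand apart (log2 -2.39, 0 genes), while 2 genes were called without HD-HR1 or CD-HR6, with 2 surrogate variables, with the share of the 10 most abundant genes as a covariate, and by DESeq2.

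**Figure D4:**
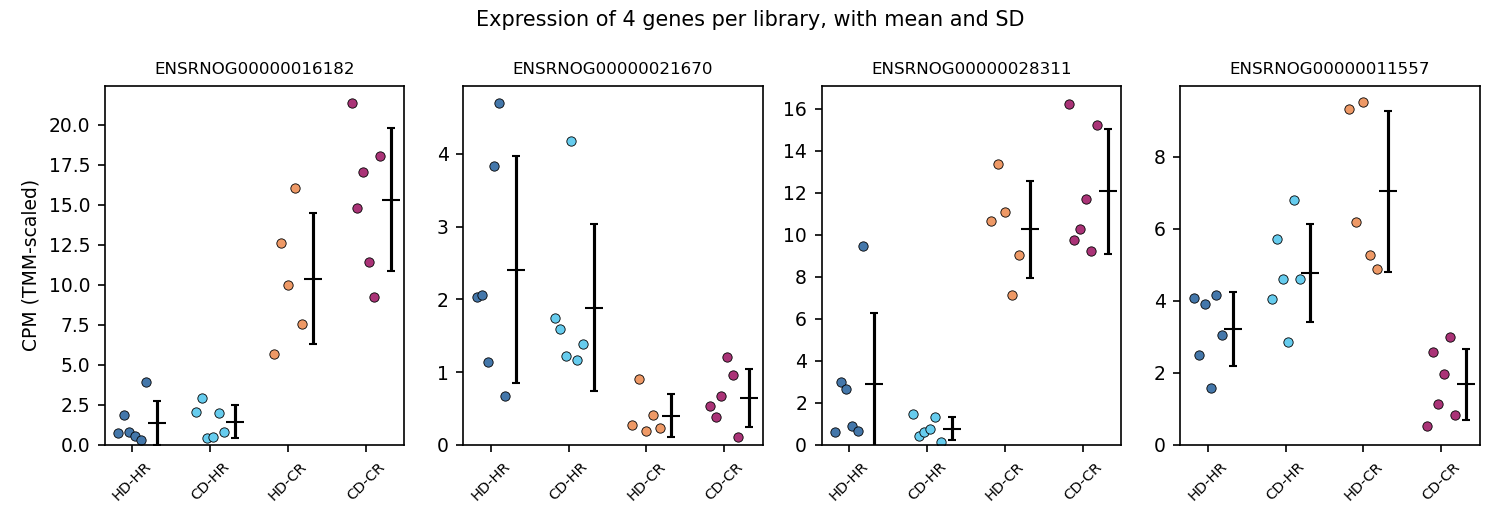
TMM-scaled CPM (vertical axes, linear) of 4 genes in the 4 groups (horizontal axes), with 1 point per library and bars of mean ± SD (n = 6, 6, 5 and 6). ENSRNOG00000016182 and ENSRNOG00000028311 were higher and ENSRNOG00000021670 lower in CKD recipients, and ENSRNOG00000011557 was lower in CD-CR than in HD-CR.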

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

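The tests of the other splits, of the libraries that stand apart, of the name prefix, of the 2 covariates and of the surrogate variables were chosen or written down after the counts of genes had been seen. In 100 groups of libraries tested for a single value far from the rest, 20 were found, where chance gives about 5. The genes among them had been picked for large changes and CPM is skewed to the right, so a surplus is built in.

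Averaged over donors, 1483 genes differed between CKD and healthy recipients, more than in any of 59 other splits of the samples (1 of 60 as large, highest other 210). The same held with CKD donors (181, highest other 5, 1 of 60) and for CKD in both (422, highest other 103, 1 of 60). These values argue against chance, although 60 splits can give no less than 1 of 60. The 71 genes with healthy donors (highest other 32, 1 of 60) are less secure when 1 library is left out. Then 24, 14, 10, 6 and 5 genes were left without HD-HR2, HD-HR3, HD-HR4, HD-CR4 or HD-CR5 and 33 to 89 without any other library, each set against splits of the full set. The 181 genes also moved, to 48 without CD-HR4, 18 without the 3 libraries that stand apart and 32 in the 2 groups alone. In the last 2 settings the 71 genes became 111 and 306. If the prefix of the animal names were the whole cause, the 2 CKD recipients of prefix 13 would lie among the 12 healthy recipients, but on a score from 200 genes chosen without the scored libraries (healthy recipients near 0, CKD recipients of prefix 12 near 1) they lay at 0.760 and 1.12 and the healthy recipients between -0.392 and 0.585 (difference 0.935, exact permutation p = 0.011, the smallest that 91 arrangements can give). The healthy recipients and the CKD recipients of prefix 12 set the 0 and the 1 of this score themselves. Their means are thus built in, and the p is approximate. The ratio of non-unique alignments as the whole cause is argued against by 1041 genes (805 of them among the 1483) called with it as a covariate. With the share of the 10 most abundant genes as a covariate 1522 genes were called. That share did not clearly differ between CKD and healthy recipients (62.4% and 60.4%, exact permutation p = 0.361). This covariate could therefore end few calls, and its count decides little. With the prefix as a covariate nearly all calls ended: the median SE rose from 0.132 to 0.245, at a median change of 0.49 before and 0.53 after. That kept size is partly built in, since the fit rests on libraries that also helped choose the 1483 genes. The prefix term of the same edgeR fit called 1 gene, with 795 genes at an unadjusted p under 0.05 where 578 would be expected by chance. It compares the 9 CKD recipients of prefix 12 with the 2 of prefix 13, so prefix effects could be missed. With 2 surrogate variables 6 genes were left, at a median change reduced to 0.24 (SE 0.151). Since the first surrogate variable differs between recipients (exact permutation p = 0.00298), a hidden factor and the recipients' own response cannot be told apart in that fit. A part played by the prefix in single genes, or a batch that follows the recipient groups, stays open beside the recipients' disease. Lasting effects on the heart of the ablation, L-NNA and NaCl that induced CKD in these recipients cannot be told apart from the disease.

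In CKD recipients 3 genes were lower with a CKD donor kidney. Each had its highest group mean in HD-CR, and for ENSRNOG00000011955 the mean of CD-CR lay between those of CD-HR and HD-HR. The difference can thus be read as a rise in HD-CR as well as a fall in CD-CR. Other splits of the HD-CR and CD-CR libraries gave at most 2 genes (1 of 60 as large). That margin is 1 gene: the real count was itself 2 without any 1 of HD-CR1, HD-CR4, HD-CR5, CD-CR2, CD-CR4 or CD-CR5, within prefix 12 and with 2 surrogate variables, while it was 3 to 18 without any other library of these groups and 12 without the 3 libraries that stand apart. The splits were run on the full set of libraries, and a margin of 1 gene is too narrow to exclude chance. The libraries that stand apart (HD-CR2 and CD-CR1 in this comparison) did not make the calls, since all 3 genes were still called without them, among 12 genes. An effect of the donor kidney is a hypothesis that stays open, beside chance and differences between the rats that the labels do not record.

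ENSRNOG00000011557 was singled out because its donor effect differed between kinds of recipient, by -2.64 on the log2 scale in the interaction test. Chance cannot be excluded for the interaction as a count, since 5 of 60 splits gave at least 1 gene, with a highest other of 23. For the donor comparisons with 0 genes this count decides nothing, since 60 of 60 splits equal a count of 0 whatever the data. Of the other splits, 1 gave 82 genes in healthy recipients and 1 gave 728 averaged over recipients, and what those splits follow was not tested.

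Other values stood far from their group. CD-CR1 had the lowest share of counts in the 10 most abundant genes (48.81%, next 63.27%) and the highest scaling factor of its group (1.462, next 0.9523), and HD-CR2 had the highest scaling factor of its group (1.319, next 0.9907). Non-unique alignments, which lie outside the gene counts, came to 10.69 per counted read in CD-HR5 (next in its group 3.67, in CD-HR2), and both values exceeded the highest of HD-HR (3.607). In HD-HR1, ENSRNOG00000048472 stood at 0.5093 CPM (next 0.1126), ENSRNOG00000008837 at 20.68 (next 7.287) and ENSRNOG00000007539 at 207.7 (next 79.38), and in HD-HR6, ENSRNOG00000028311 stood at 9.49 (next 3.004). In CD-HR1, ENSRNOG00000048472 stood at 0.8269 CPM (next 0.3462) and ENSRNOG00000010666 at 10.01 (next 1.159). CD-HR2 was high for ENSRNOG00000002224 (33.31 CPM, next 20.34), ENSRNOG00000028064 (16.32, next 5.696) and ENSRNOG00000006151 (3.716, next 1.159). CD-HR4 was high for ENSRNOG00000021670 (4.182 CPM, next 1.746) and ENSRNOG00000007030 (2.421, next 1.5), and CD-HR6 for ENSRNOG00000008168 (1.269, next 0.8275) and ENSRNOG00000018224 (2.192, next 0.6636). Among CKD recipients, HD-CR3 was high for ENSRNOG00000013408 (2.032 CPM, next 1.51), CD-CR1 for ENSRNOG00000010666 (25.83, next 8.49) and CD-CR6 for ENSRNOG00000048472 (25.38, next 4.919).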

How the results depend on the processing

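Counts are called genes, in the order averaged recipient, recipient with healthy donor, recipient with CKD donor, both, donor in healthy recipients, donor in CKD recipients, averaged donor, interaction; in the fit as designed they were 1483, 71, 181, 422, 0, 3, 0 and 1. Settings not mentioned for a comparison stayed within 1.5 times, and the cause of a change was not tested unless given. DESeq2 gave 259, 449, 651, 11, 36, 226 and 2 for all but the averaged recipient. Limma-voom gave 167 and 115 for the recipient with healthy and with CKD donor, 14 for the donor in CKD recipients and 1 for the averaged donor. The prefix covariate gave 6, 3, 0 and 0 for the recipient comparisons and both, with larger standard errors (report), and prefix 13 alone, with 2 CKD recipients, gave 0, 10, 0 and 0. With 2 surrogate variables these were 6, 0, 8 and 88, and the interaction gave 2. Only the 2 groups compared gave 306, 32 and 7 for recipient with healthy donor, recipient with CKD donor and donor in CKD recipients. No filter gave 1 for the averaged donor. Of the settings chosen after seeing the data, leaving out the 3 libraries that stand apart gave 973, 111, 18 and 219, then 12 for the donor in CKD recipients, 6 for the averaged donor and 0 for the interaction; the ratio of non-unique alignments gave 109 for the recipient with CKD donor; and the share of the 10 most abundant genes gave 47, 334, 5, 16 and 2 for recipient with healthy donor, recipient with CKD donor, donor in CKD recipients, averaged donor and interaction. Leaving out 1 library at a time gave 860 to 1742, 5 to 89, 48 to 359, 227 to 514, 0 to 1, 2 to 18, 0 to 46 and 0 to 2; the libraries that moved a count by over 1.5 times are named in the report.

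The replicate numbers did not pair the samples: deviations from the group means correlated by 0.015 on average over 33 same-numbered pairs (from -0.32 to 0.36, 12 over 0.1), against -0.0029 over 165 other pairs, and 6 of 23 libraries correlated best with their own number. With the replicate number as a block the counts were 1336, 83, 187, 423, 0, 3 and 0 in the same order to the averaged donor, and 0 for the interaction.

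Of 676 alternative values of the 25 named-gene results, 520 kept direction and side of the threshold, 129 kept the direction but no longer passed, 26 newly passed and 1 reversed: ENSRNOG00000048472 in recipients with a CKD donor, -0.3704 in prefix 13 alone, which holds 1 CD-CR library; the cause was not tested. ENSRNOG00000048472 had no value without CD-CR1, CD-CR2, CD-CR4 or CD-CR6, or in the 2 groups alone, because the filter on low counts removed it. The gene list tests and their alternatives were not run, for want of gene names. DESeq2 size factors and the filter of at least 1 CPM in at least 5 libraries, which kept 11578 genes, changed no count by over 1.5 times. At this depth and number of rats, simulated changes of 1.5-fold were recovered in 12.3 to 67.2% of genes over 6 comparisons, so small changes can be missed.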

Other observations

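The tests in this part were chosen after the counts of genes had been seen; those of the donor signature and of the position of the mixed groups were written down before their results were known, and the test of the recipient signature after the overlap of the recipient comparisons had been seen. A signature is the mean log2 CPM, signed by direction, of the 200 genes with the largest moderated statistics in 1 pair of groups, scored in the other pair, with which it shares no library.

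The donor comparisons called few genes, yet they may share a weak response across recipients. The called genes do not show it: of the 3 called in CKD recipients, 1 (33.3%) had the same direction in healthy recipients. Genes chosen between CD-CR and HD-CR scored higher with CKD donors in healthy recipients, with 0.521 ± 0.173 in CD-HR (SD, n = 6) and 0.101 ± 0.320 in HD-HR (n = 6; difference 0.42, exact permutation p = 0.0173), where 3 of 6 CD-HR libraries lay above every HD-HR library. Genes chosen between CD-HR and HD-HR separated the donors of CKD recipients, with 0.25 ± 0.208 in CD-CR (n = 6) and -0.0328 ± 0.143 in HD-CR (n = 5; difference 0.283, exact p = 0.013), where 5 of 6 CD-CR libraries lay above every HD-CR library. Over the 4 signatures tested, the Benjamini-Hochberg value of both was 0.0173. With 50 or 1000 genes the differences were 0.525 and 0.266 in healthy (exact p = 0.0368 and 0.0411) and 0.315 and 0.269 in CKD recipients (exact p = 0.013 and 0.0108), and the p-values without the 3 libraries that stand apart were 0.0281 and 0.0238. Leaving out 1 library at a time kept p at or under 0.039 in healthy recipients, while in CKD recipients 2 of the 23 omissions gave a p of 0.05 or more, 0.0671 without HD-HR5 and 0.156 without CD-HR4. The sizes are imprecise: the difference in healthy recipients ran from 0.315 to 0.744 over these omissions, the highest without HD-CR5, and that in CKD recipients from 0.19 to 0.495, the highest without HD-HR4. Across genes, the donor fold changes of the 2 recipient kinds had a Pearson correlation of 0.486 and a Spearman correlation of 0.293, and 0 of 100 relabellings reached that Pearson value (highest 0.404). A candidate explanation is a small effect of the diseased kidney on many genes, each below the threshold at this number of rats. Both signature directions and the correlation across genes measure agreement between the same 2 comparisons, so they count as 1 line of evidence. The 1477 genes at an unadjusted p under 0.05 come from the same libraries, so they are no separate support for that explanation. The prefix does not separate donors, since HD-CR holds 4 libraries of prefix 12 and CD-CR 5. Of the library measures tested, none differed between donors (smallest exact permutation p = 0.153, for the number of genes with a count). Ambiguous reads, which were not tested, were lower with CKD donors in both kinds of recipient. They averaged 1.12% in CD-HR and 1.27% in HD-HR, and 1.27% in CD-CR and 1.57% in HD-CR. The hypothesis would need other animals, and differences between donors' batches that the labels do not record stay open.

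The recipient signature carried over in the same way. Genes chosen with healthy donors gave 1.33 ± 0.286 in CD-CR (n = 6) and 0.549 ± 0.407 in CD-HR (n = 6), with a difference of 0.781 and an exact p = 0.00216, the smallest that 924 arrangements of equal groups can give in a two-sided test, and all 6 CD-CR libraries lay above all CD-HR libraries. Genes chosen with CKD donors gave 1.2 ± 0.109 in HD-CR (n = 5) and 0.528 ± 0.204 in HD-HR (n = 6; exact p = 0.00433), with all 5 HD-CR libraries above all HD-HR libraries. With 50 or 1000 genes the differences were 1.2 (exact p = 0.0152) and 0.467 (exact p = 0.00216) with CKD donors, and 1.13 and 0.475 (both exact p = 0.00433) with healthy donors. With 200 genes, leaving out 1 library at a time kept both p-values at or under 0.00866. Because the prefix runs with the recipient in both donor kinds, most of this carry-over does not separate the recipients' disease from the prefix. The CKD recipients of prefix 13, HD-CR5 and CD-CR5, lay above all healthy recipients with the same kind of donor. This argues against the prefix as the whole cause, on 1 library per donor kind, and a part played by it stays open.

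Whether a healthy kidney moves the heart of a CKD recipient back towards HD-HR was asked on a scale set by held-out libraries, with HD-HR near 0 and CD-CR near 1. The means of HD-HR and CD-CR are thus built in, and p-values against these groups are approximate. HD-CR lay at 0.811 ± 0.228 (SD, n = 5) and CD-CR at 1.01 ± 0.251 (n = 6), a difference of -0.197 with an exact p = 0.208. CD-HR lay at 0.276 ± 0.409 (n = 6) and HD-HR at 0.000535 ± 0.121 (n = 6), a difference of 0.275 with an exact p = 0.156. Neither passed, so these data leave both questions open: HD-CR was on average closer to CD-CR than to HD-HR, but a partial move of the size of the difference could not be told from none with 5 and 6 rats. The mean of HD-CR exceeded that of CD-HR by 0.535 on this scale (exact p = 0.0346, Benjamini-Hochberg 0.104 over 3 tests, which does not pass), and the groups overlapped, with CD-HR2 at 0.753 and HD-CR1 at 0.483. The scale carries the prefix as well, since HD-HR and CD-HR hold prefix 13 alone while 5 of 6 CD-CR and 4 of 5 HD-CR libraries have prefix 12, so a prefix effect would also place HD-CR near CD-CR and above CD-HR.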
